A study of Homo sapiens with 5 samples.

How the data were processed

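RNA sequencing of MDA-MB-231 cells gave 5 libraries, 1 for each condition: 20% O2 for 1 day, 1% O2 for 1 day, 20% O2 for 10 days, 1% O2 for 10 days, and 10 days at 1% O2 followed by 10 days at 20% O2 (reoxygenated). Per the labels' protocols, column-purified RNA was made into libraries with an mRNA kit. The strand setting and the annotation are not given in the sources used here. Per the submitters' processing notes, Bowtie2 2.1.0, RSEM 1.2.15 and edgeR were used with the hg38 build.

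The authors deposited a table of expected counts per gene symbol, with 26475 rows, estimated and not normalized. Between 3.58% and 4.09% of its values in a library were not whole. Totals per library ran from 7719797 to 12544953, so that 1 read corresponds to 0.0816 to 0.126 CPM and an absence of counts allows up to 3 counts, or 0.245 to 0.377 CPM. The authors also deposited a table of normalized values (a signal on a CPM scale with TMM factors), per the file's name and values. All of its values were whole-read multiples that match the rounded expected counts, so it adds no reads of its own and was used only as an alternative, as log2(value + 1). Symbols of 28 rows had been turned into dates by a spreadsheet. No mitochondrially encoded gene was among the rows. Reads were shared out between genes by the authors' estimation, so rows of near-identical or overlapping genes can trade reads between libraries.

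Expected counts were rounded to whole numbers. Genes with at least 1 CPM in at least 1 of the 5 libraries were kept, which left 13940. TMM factors (edgeR 4.0.16 in R 4.3.3) were 0.965, 0.965, 0.977, 1.067 and 1.03 in the order of conditions above, and log2 CPM values were computed with a prior count of 2. With 1 library per condition, each difference is a log2 difference between a pair of libraries and has no test; it compares those libraries, not the conditions. A size rule of log2 1 (2-fold) described how many genes lay apart. Exact Clopper-Pearson 95% intervals of the count ratio, and Poisson intervals of single levels, cover counting error only, because each condition had 1 library. Reads were not marked with molecular identifiers, so amplified copies could not be told apart and the intervals may be too narrow. The number of genes that counting noise alone puts past the size rule was simulated for each pair. Tested on simulated pairs at the depth of the day 10 libraries (13940 genes), the size rule found 49 of 100 genes changed 2-fold and 99 of 100 changed 4-fold at a dispersion of 0.0193, and 230 unchanged genes passed it. The rule is itself a 2-fold cut, so about even odds for genes changed 2-fold follow from the rule.

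Both 1% O2 libraries and both 20% O2 libraries of day 1 and day 10 were also compared with edgeR's quasi-likelihood test, with oxygen and day as terms, TMM factors, genes with at least 1 CPM in at least 2 of the 4 libraries (13011) and Benjamini-Hochberg adjustment at 0.05. The model leaves 1 residual degree of freedom, to which edgeR adds 29.8 prior degrees of freedom shared across genes. Its common dispersion was 0.0484. The labels do not say that the libraries of different days are independent cultures, so p-values measure the spread between these libraries only. Tested on simulated data of that design (13011 genes), it recovered 95%, 92% and 32% of 100 genes changed 2-fold at dispersions of 0.01, 0.019 and 0.048, and 100% of 100 genes changed 4-fold at each, with 3, 9 and 6 false calls. Changed genes were drawn from the better counted genes, had the same fold on both days and shared 1 dispersion with all others. A difference in fold between days was not simulated, so these values do not cover genes that changed differently on each day.

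Before the data were examined, 24 gene lists, the size rule, the tests and the rule for named genes were set. Named genes were the 10 highest and 10 lowest in the acute and chronic differences, the 8 highest and 8 lowest in the chronic minus acute and reoxygenated differences (CPM of at least 5 and an interval that excludes 0, without uncharacterized, small RNA and antisense symbols), the 5 lowest adjusted p per direction of the oxygen term, up to 4 members per list, and a fixed panel. Members of small counts, such as VLDLR, are also named, and genes chosen after their values were seen are described as such. List medians were set against 10000 random lists of equal size, matched on mean expression in 20 bins; this describes the libraries and is not a test. Genes were matched to a RefSeq table of the GRCh38 assembly for coordinates (13699 of 13940 symbols). Sharing of sequence was measured as the percentage of sampled 50-base words of a gene's transcripts found in another gene, and 500 genes had a joined name or at least 50% shared.

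Retention after reoxygenation was the share of genes past the size rule after 10 days at 1% O2 that passed it in the same direction in reoxygenated cells; cells that had returned fully were simulated 100 times at the dispersion of 0.0193 seen between both 20% O2 libraries. Alternatives were DESeq2 size factors (DESeq2 1.42.0), library totals, no filter or a filter of 5 CPM, prior counts of 0.5 and 10, the authors' normalized values, DESeq2 and limma-voom (limma 3.58.1) tests, no day term, each library left out, all 5 libraries, and, chosen after seeing the data, leaving out genes that share sequence. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.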

Results

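RNA sequencing was used to measure gene expression in MDA-MB-231 cells, an established line of human triple-negative breast cancer with a mesenchymal character. The series asks how a short exposure to low oxygen (acute hypoxia, 1 day) differs from a long one (chronic hypoxia, 10 days), and what remains after oxygen is restored. It holds 5 libraries with 1 per condition: cells kept for 1 day at 20% O2 or at 1% O2, for 10 days at 20% O2 or at 1% O2, and reoxygenated cells that spent 10 days at 1% O2 followed by 10 days at 20% O2. The deposited estimated counts summed to 10764207 for 20% O2 at day 1, 11189152 for 1% O2 at day 1, 12544953 for 20% O2 at day 10, 9781980 for 1% O2 at day 10 and 7719797 for the reoxygenated cells. With 1 library per condition, the pairwise differences had no replicate check, and no p-value across genes was computed for them. Intervals given with a log2 difference are exact 95% intervals of the count ratio and cover counting error only, not the variation between cultures. A gene was called higher or lower when its log2 difference was at least 1 in size, and 13940 genes were compared. Between both 20% O2 libraries, which differed in time but not in oxygen, 609 genes passed this size rule, and this pair served as a yardstick.

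After 1 day at 1% O2, the genes higher than at 20% O2 included known targets of the hypoxia-inducible factors, the transcription factors that are stabilized when oxygen is low. CA9 (carbonic anhydrase 9, an enzyme of pH regulation; chromosome 9, 35673928 to 35681159) had 53 counts at 20% and 560 at 1% O2, a log2 difference of 3.30 (2.94 to 3.78), or 9.83-fold. NDRG1 (chromosome 8, 133237175 to 133297252) was 8.62-fold higher, with a log2 difference of 3.11 (3.00 to 3.23). The glycolytic aldolase gene ALDOC was higher by a log2 difference of 2.13 (1.95 to 2.33). The lipoprotein lipase inhibitor gene ANGPTL4 was higher by 2.13 (1.70 to 2.71) and SPAG4 by 2.25 (11 and 62 counts). HIF1A, which encodes the oxygen-regulated subunit HIF-1α (chromosome 14, 61695513 to 61748258), was lower at 1% O2, with a log2 difference of −1.05 (−1.13 to −0.98), whereas EPAS1, which encodes HIF-2α, differed by −0.07 (−0.25 to 0.10).

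The fixed list of 38 measured hypoxia-inducible factor targets outside glycolysis had a median log2 difference of 1.10 after 1 day, with 20 members higher, none lower, and all 38 above 0. Among 10000 random lists matched on expression, the central 95% of medians ran from −0.08 to 0.08. Glycolysis and lactate export had a median of 0.60 (random range −0.10 to 0.08), with 5 of 24 genes past the size rule, among them the kinase gene PFKFB4 at 1.76 (1.48 to 2.07) and PDK1, which restrains entry of pyruvate into mitochondria, at 1.07 (0.86 to 1.29). Smaller shifts outside the random range were seen for histone lysine demethylases (median 0.17, with KDM3A at 1.22 (1.06 to 1.39)), NF-kB and inflammatory cytokine genes (0.17), extracellular matrix and invasion genes (0.17), cholesterol and fatty acid synthesis (0.12), mesenchymal genes (0.12) and interferon sensing and signalling (0.11). Medians lay below the random range for DNA replication (−0.21), nuclear-encoded oxidative phosphorylation (−0.16), NRF2 targets (−0.16) and ribosomal proteins (−0.15). The last 4 lists were also below their random range between the 20% O2 libraries of day 10 and day 1, at −0.15, −0.15, −0.12 and −0.23. Of the lists with raised medians, NF-kB (0.57), mesenchymal (0.24) and matrix genes (0.21) were likewise above their random range between those libraries. So were interferon signalling genes (0.17) and the hypoxia-inducible factor targets (0.10). Both comparisons subtract the same 20% O2 library of day 1. A shift in that library alone could therefore give both the same direction. The interferon-stimulated genes (−0.05), mitotic genes (−0.07), double-strand break repair genes (−0.03), MHC class I genes (−0.03), immune ligands (0.12), integrated stress response genes (0.00), endoplasmic reticulum chaperones (0.08), luminal markers (−0.01), immediate early genes (0.03) and the oxygen sensing core (−0.06) stayed within theirs.

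In total 295 genes were higher and 117 lower after 1 day, fewer than the 609 between the 20% O2 libraries, and simulated counting noise alone put 182.5 genes past the rule. Restricted to genes with at least 5 CPM (counts scaled to library depth) in 1 or more libraries, 109 were higher and 22 lower, against 15.5 from counting noise. Several of the largest differences belonged to genes whose reads could not be assigned with certainty. COMMD3-BMI1, with 0 counts at 1% O2, POC1B-GALNT4 (117 and 0 counts) and TVP23C-CDRT4 (6 and 58) carry joined names of neighbouring genes. FAM225A (132 and 62), FAM225B (18 and 107), NOMO3 (175 and 52), RN7SL2 (222 and 102) and KIAA0408 (59 and 28) have most of their sampled words in another gene. BLOC1S5 (191 and 84) and HNRNPH2 (95 and 449) overlap transcripts with joined names. H3F3A (54 and 0) shared 8.9% of its sampled words and is uncertain for another reason, that it had counts in 1 of the 5 libraries only. Summed with their partners, the COMMD3 and BMI1 rows differed by −0.02 and the POC1B and GALNT4 rows by −0.03. TCAF2, at a log2 difference of 2.33 (1.85 to 2.99), shares 48.3% of its sampled 50-base words with other genes.

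After 10 days at 1% O2 the differences were wider. NDRG1 had 1014 counts at 20% O2 and 40452 at 1% O2, a 46.8-fold difference (log2 5.55, 5.46 to 5.64). The death ligand gene TNFSF10 (TRAIL; chromosome 3, 172505508 to 172523430) was 35.2-fold higher, from 41 to 1296 counts (log2 5.14, 4.77 to 5.70), and the cytokine gene TNFSF15 was 26.2-fold higher (log2 4.71, 4.50 to 4.97). The myo-inositol transporter gene SLC5A3 was higher by 4.84 (4.74 to 4.95); it overlaps MRPS6, and both rows together were higher by 4.42. ANGPTL4 was higher by 4.51 (4.20 to 4.93), the glucose transporter gene SLC2A3 by 4.32 (4.18 to 4.47) and LOX, which encodes the collagen cross-linking enzyme lysyl oxidase, by 3.92 (3.80 to 4.07). The prolyl hydroxylase gene EGLN3 was higher by 3.86 (3.52 to 4.34) and VEGFA, which encodes an angiogenic growth factor, was 5.67-fold higher. CASP14 (4 and 140 counts), ZNF467 (2 and 67) and ACKR3 (2 and 63) were higher from low counts at 20% O2, with intervals of 3.97 to 7.26, 3.39 to 8.37 and 3.30 to 8.29.

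Genes lower after 10 days at 1% O2 included HIF1A itself, at 5727 and 820 counts (log2 −2.57, −2.68 to −2.47). The short non-coding RNA gene BCYRN1 was lower by −4.11 (−5.06 to −3.56), the granulocyte growth factor gene CSF3 by −3.08 (−4.51 to −2.36), and TAF9B by −3.04 (−3.65 to −2.62); the TAF9 and TAF9B rows together were lower by −1.14. OXCT1, which encodes an enzyme of ketone body use, was lower by −2.92 (−3.26 to −2.64), ID3 by −2.76 (−3.12 to −2.47) and NQO1, a target of the oxidative stress regulator NRF2, by −2.58 (−2.79 to −2.40). SMN2 (710 and 10 counts), SGK3 (124 and 0), EEF1E1-BLOC1S5 (161 and 0), TMEM256-PLSCR3 (0 and 221) and the pseudogene HNRNPA1P33 (165 and 21) were also among the most different rows and are uncertain, because they share sequence with near-identical or overlapping genes. The SMN1 and SMN2 rows together differed by −0.60, and the SGK3 rows by −1.52.

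**Figure D1:**
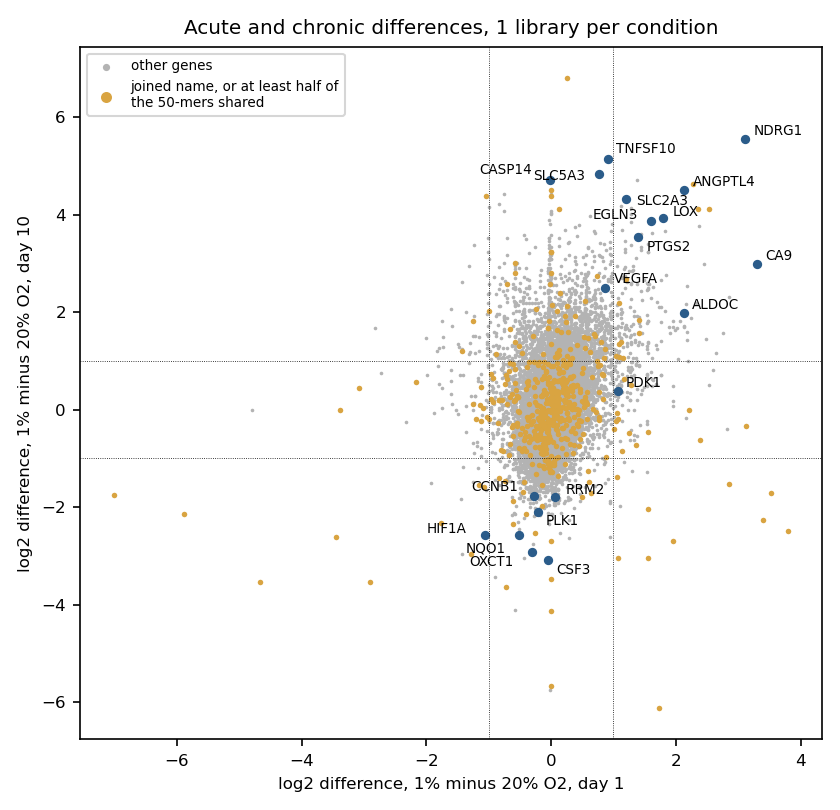
Each point is 1 of 13940 genes, with its log2 difference between 1% and 20% O2 after 1 day on the horizontal axis and after 10 days on the vertical axis; dotted lines mark the size rule of 1, blue points are named genes and orange points are genes with a joined name or at least 50% of their 50-base words shared with another gene. CA9 lies at 3.30 and 2.99, NDRG1 at 3.11 and 5.55, TNFSF10 at 0.91 and 5.14, and HIF1A at −1.05 and −2.57.

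Genes of cell division were lower after 10 days at 1% O2. All 38 mitotic genes were below 0, 28 of them past the size rule, with a median log2 difference of −1.17 (random range −0.50 to −0.04). PLK1, which encodes a mitotic kinase, was lower by −2.11 (−2.29 to −1.95), the kinetochore motor gene CENPE by −1.96 (−2.11 to −1.83) and CCNB1, which encodes cyclin B1, by −1.76 (−1.87 to −1.66); the proliferation marker gene MKI67 differed by −1.01 (−1.07 to −0.96). All 42 DNA replication genes were below 0, 20 past the rule, with a median of −0.97 (random range −0.44 to 0.01), including the ribonucleotide reductase gene RRM2 at −1.78 (−1.88 to −1.69). Double-strand break repair genes had a median of −0.71 (random range −0.45 to 0.10), with 10 of 28 lower, such as BARD1 at −1.69 (−1.97 to −1.45) and BRCA1 at −1.17 (1053 and 398 counts).

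The hypoxia-inducible factor targets had a median log2 difference of 1.69 after 10 days, with 29 of 38 higher and none lower, and glycolysis and lactate export a median of 0.41, with 6 of 24 higher. Immediate early genes had a median of 0.90 (random range −0.42 to 0.29), with 9 of 20 higher, including the phosphatase gene DUSP1 at 2.00 (1.92 to 2.08), and 1 lower, FOSL1, at −1.65 (−1.77 to −1.53). Extracellular matrix and invasion genes had a median of 0.66, with 11 of 38 higher and 2 lower; the collagenase gene MMP1 was higher by 1.49 (1.46 to 1.52) and the fibronectin gene FN1 by 1.96 (1.90 to 2.02). Medians above the random range were also seen for integrated stress response genes (0.44, with CEBPB at 1.55 (1.44 to 1.67) and ATF5 at −1.91 (−2.28 to −1.60)), cholesterol synthesis (0.39, with MSMO1 at 1.73 (1.63 to 1.85)), histone lysine demethylases (0.29, with KDM7A at 2.32 (2.06 to 2.62)) and endoplasmic reticulum chaperones (0.16, upper limit of the random range 0.16). Oxidative phosphorylation genes had a median of −0.38 (random range −0.34 to 0.00), with 68 of 78 below 0 and cytochrome c, CYCS, at −1.24 (−1.32 to −1.17). Ribosomal protein genes had a median of −0.13, which lay above that of equally abundant genes (random range −0.49 to −0.20).

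Medians of the remaining lists stayed within their random range after 10 days at 1% O2. These were interferon-stimulated genes (0.16), interferon sensing and signalling (−0.08), MHC class I genes (0.09), immune ligands (0.23, with TNFSF10 the member of highest difference), NRF2 targets (−0.44), mesenchymal genes (0.13), luminal markers (0.46), the oxygen sensing core (−0.05) and NF-kB and inflammatory cytokine genes (−0.06). The last list was split, with 8 of 32 members higher and 7 lower. PTGS2, which encodes the prostaglandin-forming enzyme COX-2, was higher by 3.54 (3.38 to 3.73) and the chemokine gene CXCL1 lower by −2.53 (−2.73 to −2.35). Of 16 markers of fibroblasts, endothelium, blood and liver, 5 passed the expression filter, and their median of 1.11 lay within the random range (−0.30 to 1.99); CD14 had 15 and 40 counts and PTPRC 14 and 28. No mitochondrially encoded transcript was among the rows analysed here.

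After 10 days 2011 genes were higher and 982 lower, against 113.5 from counting noise, and 67.2% of these 2993 genes were higher. With library totals in place of TMM factors that share was 77.8%. With the stricter filter of 5 CPM, 1319 genes were higher and 668 lower. The 1% O2 library of day 10 also had the largest share of ribosomal RNA counts, 2.17% against 1.51% to 1.78% in the other 4 libraries, and the most rows with a count, 16748.

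**Figure D2:**
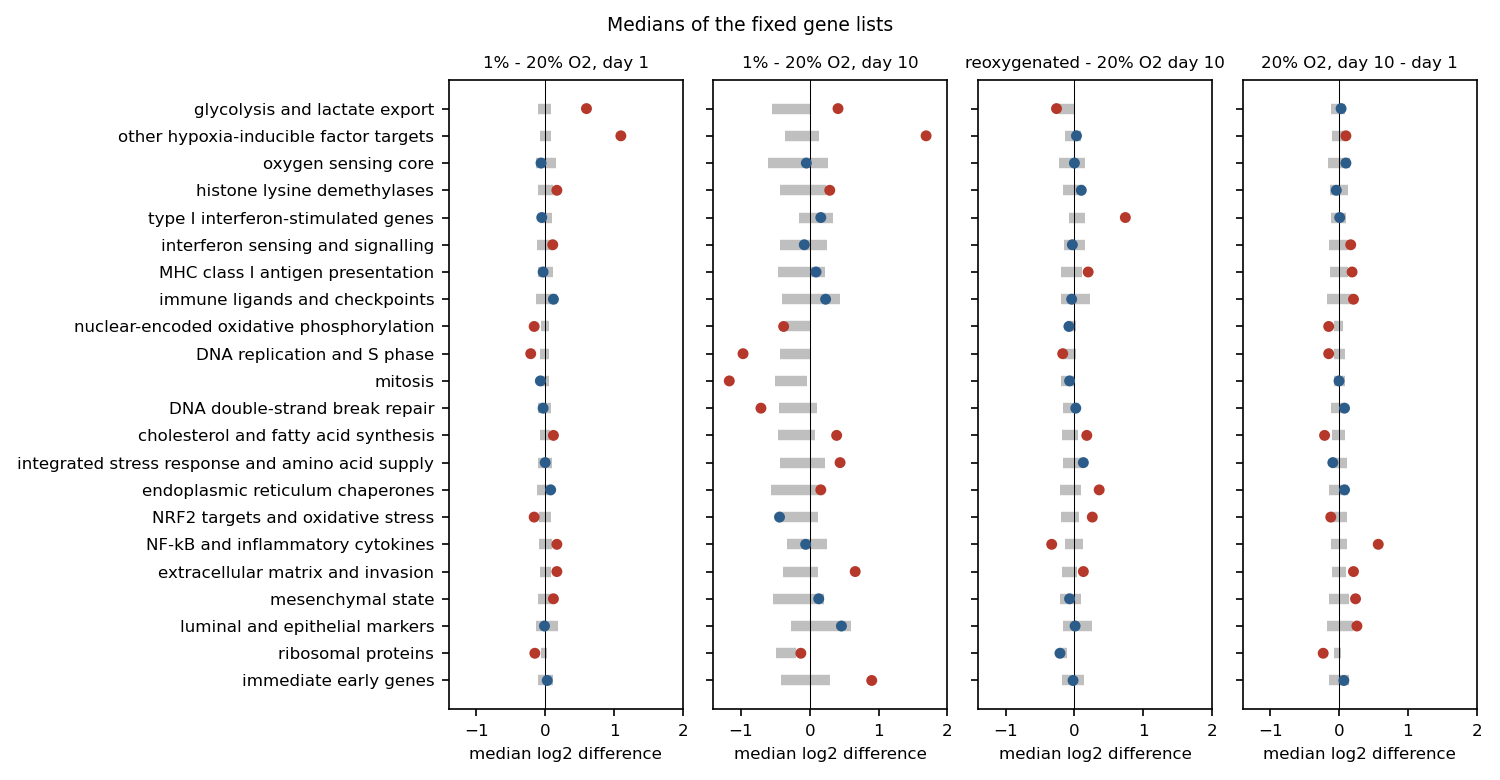
Median log2 difference of each fixed gene list except the markers of other cell types (points) in 4 comparisons, with the central 95% of 10000 random lists matched on expression as grey bars; red points lie outside that range. Hypoxia-inducible factor targets stand at 1.10 and 1.69 after 1 and 10 days at 1% O2, mitotic genes at −1.17 after 10 days, and interferon-stimulated genes at 0.74 in reoxygenated cells.

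The direct contrast of chronic with acute hypoxia, the difference of the day 10 and day 1 differences, put 1747 genes higher and 862 lower, with 67.0% higher (78.2% with library totals). TNFSF10 was higher by 4.23 in this contrast, SLC5A3 by 4.06, CASP14 by 4.73 and SLC2A3 by 3.12, whereas CA9 differed by −0.31, ALDOC by −0.15 and KDM3A by 0.09. Mitotic genes (median −1.14, 26 of 38 lower), replication genes (−0.77, 13 of 42 lower) and repair genes (−0.72, 8 of 28 lower) lay below their random ranges, and the hypoxia-inducible factor targets (0.76, 14 of 38 higher) and immediate early genes (0.79, 7 of 20 higher) above theirs. Matrix (0.35), integrated stress response (0.26), cholesterol synthesis (0.22) and ribosomal protein genes (0.06) were also above theirs, and glycolysis (−0.15) stayed within its range. Of the 295 genes higher after 1 day, 177 were also higher after 10 days, against 42.6 for independent lists. Of the 117 lower after 1 day, 18 were also lower after 10 days, against 8.2 for independent lists, and 43 were higher, against 16.9. The values for independent lists do not allow for expression level. With the filter of 5 CPM, 22 genes were lower after 1 day, so most of the 117 were expressed below that filter. Across genes, which are not independent replicates, both differences correlated with Pearson's r = 0.29 and Spearman's rho = 0.33; they share no library.

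Taking the 4 libraries of both days together, CA9, NDRG1, ANGPTL4, CCNG2 and LOX rose and HIF1A fell at 1% O2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the day as covariate. CA9 rose by a log2 change of 3.19 (SE 0.31, adjusted p = 2.86e-07), NDRG1 by 4.35 (SE 0.47, adjusted p = 1.13e-06), ANGPTL4 by 3.48 (SE 0.41, adjusted p = 3.85e-06), CCNG2 by 2.34 (adjusted p = 2.48e-05) and LOX by 2.88 (SE 0.38, adjusted p = 2.48e-05) in this edgeR test, and HIF1A fell by 1.79 (SE 0.32, adjusted p = 0.00216). Each change had 1 direction on both days. Of 13011 genes tested, 117 rose and 13 fell, and 1593 had an unadjusted p under 0.05. The other fallen genes included NQO1, OXCT1, TAF9B and BCYRN1, and also SMN2, COMMD3-BMI1, NOMO3, RAD51L3-RFFL, URGCP-MRPS24, RN7SL2 and RTEL1, which are uncertain because they share sequence with other rows; without such genes 110 rose and 6 fell. The TAF9 and TAF9B rows together differed by −0.07 after 1 day and −1.14 after 10 days at 1% O2. The model had 1 residual degree of freedom, which holds the difference between days together with the noise. Each gene's spread was weighted with 29.8 prior degrees of freedom shared across genes. A gene's own difference between days thus had little weight, and called genes such as NDRG1 moved by different amounts on each day. With all 4 libraries but without the day term, edgeR called 0 genes, with 462 at an unadjusted p under 0.05, and DESeq2 and limma-voom with the day term called 49 and 224. In fits of 3 libraries, which dropped a library and the day term together, the count was 0 when the 20% O2 library of day 1 was left out, 4225 without 1% O2 at day 1, 0 without 20% O2 at day 10 and 22 without 1% O2 at day 10.

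By list, 21 of 38 hypoxia-inducible factor targets rose in edgeR's test over all genes, and 37 rose when adjusted over the list alone. For glycolysis and lactate export 4 of 24 rose (ALDOC, SLC2A3, PFKFB4 and ENO2), and 11 adjusted over the list alone. Among histone lysine demethylases KDM3A and KDM7A rose, and 5 of 20 adjusted over the list alone; among integrated stress response genes VLDLR and GDF15 rose, and 3 of 21 adjusted over the list alone. DESeq2 called 16 hypoxia-inducible factor targets, 3 glycolysis genes, 1 demethylase and 1 integrated stress response gene, and limma-voom 25, 4, 2 and 2. TNFSF10 alone of 15 immune ligands, MSMO1 alone of 30 cholesterol synthesis genes, PTGS2 alone of 31 NF-kB genes and FN1 alone of 35 matrix genes rose, and 1, 1, 4 and 3 did adjusted over the list alone, with 1 NF-kB gene, CXCL1, falling. DESeq2 called 0, 0, 1 and 0 genes of these 4 lists and limma-voom 1, 1, 3 and 2. NQO1 fell among 26 NRF2 targets, and 2 fell adjusted over the list alone, with 0 called by DESeq2 and 1 by limma-voom. HIF1A was the 1 fallen gene of 10 in the oxygen sensing core by both counts. None of 38 mitotic genes passed over all genes in edgeR's test, while 3 fell adjusted over the list alone; 20 had an unadjusted p under 0.05, all lower, and DESeq2 called 0 and limma-voom 1. None of 42 replication genes passed by either adjustment, 20 had an unadjusted p under 0.05, all lower, and DESeq2 and limma-voom called 0. For immediate early genes edgeR called 0 of 19, with 2 rising and 1 falling adjusted over the list alone and 9 at an unadjusted p under 0.05, and for endoplasmic reticulum chaperones 0 of 16, with 1 rising adjusted over the list alone and 2 at an unadjusted p under 0.05; DESeq2 and limma-voom called 0 of either. edgeR called 0 over all genes and 0 adjusted over the list alone for interferon-stimulated genes, interferon signalling, MHC class I, oxidative phosphorylation, repair, mesenchymal, luminal, other cell type and ribosomal protein lists. In that order, these had 3, 0, 2, 4, 3, 2, 4, 0 and 0 genes at an unadjusted p under 0.05; DESeq2 called 0 in each, and limma-voom 1 luminal gene and 0 in the others.

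In reoxygenated cells, compared with 10 days at 20% O2, interferon-stimulated genes were higher: 19 of 53 passed the size rule, none was lower, and 45 were above 0, with a median log2 difference of 0.74 (random range −0.08 to 0.16). The RNA helicase gene DDX60 (chromosome 4, 168216294 to 168325979) went from 195 to 601 counts, a log2 difference of 2.24 (2.01 to 2.49). OASL was higher by 2.00 (1.70 to 2.34), the antiviral gene IFIT1 (chromosome 10, 89392623 to 89406487) by 1.95 (1.79 to 2.13), MX2 by 1.71 (21 and 48 counts) and the ubiquitin-like modifier gene ISG15 by 1.46 (1.19 to 1.76). MX1, at 0.92 (0.47 to 1.43), did not pass the rule. The chemokine gene CCL5, with 14 and 57 counts, was higher by 2.46 (1.79 to 3.61). The interferon sensing and signalling list had a median of −0.03. Against the 20% O2 library of day 1, the interferon-stimulated genes had a median of 0.68, with 15 of 53 higher.

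CYP1B1, which encodes a cytochrome P450 enzyme, was 4.90-fold higher in reoxygenated cells than at 20% O2 (log2 2.29, 2.15 to 2.44), the filaggrin gene FLG was higher by 2.14 (1.83 to 2.51) and the stress cytokine gene GDF15 by 1.97 (1.68 to 2.32). CST1 (−3.13, −4.60 to −2.33) and ALPPL2 (−3.71, −6.57 to −2.67) were lower than at 20% O2 on day 10, but both had been higher in that library than on day 1 (2.59 and 2.57). Against day 1 they differed by −0.53 (−2.05 to 0.69) and −1.14 (−3.97 to 0.43). RGPD8 (0 and 55 counts), MAGEA2B (114 and 4) and PDXDC2P (27 and 81) were also among the most different rows and have near-identical copies. NF-kB and inflammatory cytokine genes had a median of −0.33, with 5 of 32 lower and 3 higher, among them CXCL8 at −1.32 (−1.39 to −1.26) and CXCL1 at −1.19 (−1.34 to −1.05). Against the 20% O2 library of day 1 the direction of this list was opposite, with a median of 0.20 (random range −0.16 to 0.17), 7 higher and none lower, and CXCL8 and CXCL1 differed by −0.45 and −0.24. Medians lay above their random ranges for endoplasmic reticulum chaperones (0.36, with HERPUD1 at 1.23 (1.04 to 1.43)), NRF2 targets (0.26, with the cystine transporter gene SLC7A11 2.08-fold higher), MHC class I genes (0.20), cholesterol synthesis (0.18) and extracellular matrix genes (0.13), and below them for glycolysis (−0.26) and replication (−0.17). The hypoxia-inducible factor targets (0.03), demethylases (0.10), mitotic genes (−0.07), repair genes (0.02), oxidative phosphorylation (−0.08), ribosomal proteins (−0.21), immediate early genes (−0.02), integrated stress response (0.13), immune ligands (−0.04), mesenchymal genes (−0.07), luminal markers (0.01), the oxygen sensing core (0.00) and other cell types (0.17) stayed within theirs. Against the 20% O2 library of day 1, cholesterol synthesis (−0.10) and glycolysis (−0.12) were instead within their ranges, whereas hypoxia-inducible factor targets (0.13) and mesenchymal genes (0.21) were above theirs and oxidative phosphorylation (−0.27) and ribosomal proteins (−0.44) below. In total 474 genes were higher and 197 lower, against 194.5 from counting noise and 609 between the 20% O2 libraries. The reoxygenated cells had spent 10 days longer in culture than their 20% O2 comparator, so oxygen history and time in culture were not separated.

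Compared with 10 days at 1% O2, reoxygenated cells had 781 genes higher and 1556 lower. NDRG1 was lower by −5.93, TNFSF10 by −5.22, CA9 by −4.17 and LOX by −4.15, and all 38 hypoxia-inducible factor targets were below 0 (median −1.52, 30 past the size rule). Medians also lay below their random ranges for immediate early genes (−0.91), glycolysis (−0.71), matrix genes (−0.39, 7 of 38 lower), integrated stress response (−0.33), NF-kB genes (−0.30), the oxygen sensing core (−0.27), cholesterol synthesis (−0.16) and ribosomal proteins (−0.12). They lay above for mitotic (1.13, 26 of 38 higher), replication (0.81), repair (0.70) and NRF2 genes (0.58), with HIF1A higher by 2.99 and NQO1 by 3.41. Interferon-stimulated genes had a median of 0.58 in this comparison, above the random range, with 17 of 53 higher and 2 lower.

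**Figure D3:**
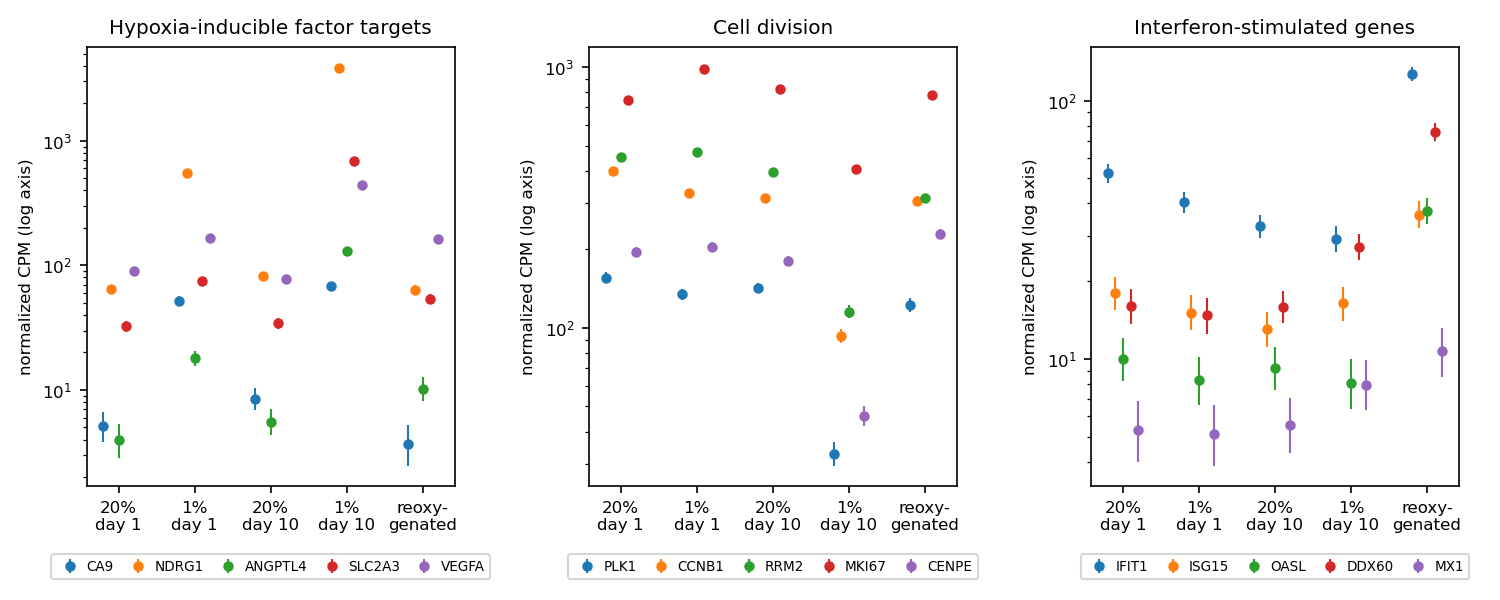
Normalized CPM on a log axis in each of the 5 libraries (1 per condition) for 5 hypoxia-inducible factor targets, 5 genes of cell division and 5 interferon-stimulated genes; bars are 95% Poisson intervals and cover counting error only. NDRG1 reached 3879 CPM at 1% O2 on day 10 and 63.4 in reoxygenated cells, PLK1 32.9 and 122, and IFIT1 29.2 and 127.

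Of the 2011 genes higher after 10 days at 1% O2, 314 (15.6%, 14.1% to 17.3% by the exact binomial method) were still higher in reoxygenated cells by the size rule, and 1032 (51.3%) lay within a log2 difference of 0.5 of the 20% O2 level. Of the 982 lower genes, 37 (3.8%, 2.7% to 5.2%) were still lower and 792 (80.7%) were back within 0.5. These binomial intervals treat genes as independent replicates, which they are not. They do not cover the variation between cultures or the choice of reference and filter. Both differences share the 20% O2 library of day 10, and in simulated cells that had returned fully, 4.1% and 1.1% would have been counted as retained. That simulation gave all genes the same dispersion, 0.0193. In simulated pairs at that dispersion 230 unchanged genes passed the size rule, against 609 between the 20% O2 libraries, which also differed in time. The simulated 4.1% and 1.1% may therefore be too low. Against the 20% O2 library of day 1, 23.1% of the higher and 3.0% of the lower genes were retained, and with the filter of 5 CPM 9.3% and 1.8%. Without genes that share sequence, 15.4% and 2.0% (18 of 922) were retained. PTGS2 was among the retained genes, at 3.54 after 10 days at 1% O2 and 1.95 (1.76 to 2.15) after reoxygenation, as were VEGFA at 5.67-fold and 2.09-fold and GDF15 at log2 differences of 2.39 and 1.97. Across genes, the chronic and reoxygenated differences correlated with r = 0.40, and simulation without any effect gave 0.46 from the shared library. The covariance was 0.176 against 0.067 simulated at that same dispersion, a difference of 0.109. With the 20% O2 library of day 1 as the reference of the reoxygenated cells, which removes the shared library, r was 0.33 and the covariance 0.182.

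Between day 1 and day 10 at 20% O2, 426 genes were higher and 183 lower at day 10, against 177.5 from counting noise. NF-kB and inflammatory cytokine genes had a median log2 difference of 0.57 (random range −0.11 to 0.12), with 26 of 32 above 0 but 3 higher by the size rule. CXCL1 stood at 0.95 (0.83 to 1.07), CXCL8 at 0.88, both short of the rule, and CSF3 at 1.14. EPAS1 was higher by 1.29. Medians also lay above their random ranges for luminal markers (0.26), mesenchymal genes (0.24), matrix genes (0.21), immune ligands (0.21), MHC class I (0.19), interferon signalling (0.17) and hypoxia-inducible factor targets (0.10). They lay below for other cell types (−0.88, 5 genes), ribosomal proteins (−0.23), cholesterol synthesis (−0.21), oxidative phosphorylation (−0.15), replication (−0.15) and NRF2 targets (−0.12). Glycolysis (0.03), demethylases (−0.04), interferon-stimulated genes (0.01), mitosis (0.00), repair (0.08), integrated stress response (−0.09), chaperones (0.08), immediate early genes (0.07) and the oxygen sensing core (0.10) stayed within theirs.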

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

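Leaving out genes that share sequence was added after seeing the data. Past the size rule in both comparisons, 14 genes were higher after 1 day and lower after 10 days at 1% O2, against 20.8 for independent lists. Another 43 were lower and then higher, against 16.9 for independent lists. Of the genes in both groups, 6 are among those named by the rule set beforehand. With 1 library per condition, the difference between the times was not tested. EEF1E1-BLOC1S5 had a chronic minus acute log2 difference of −7.85, GTF2H2C one of −5.25 and TVP23C-CDRT4 one of −4.38. BLOC1S5, which overlaps the first of these, had 2.39. C9orf84 went from 5 to 1 counts at day 1 and from 9 to 99 at day 10, a contrast of 4.62. Its day 1 counts lie near the floor of 3 counts, so its direction at day 1 is uncertain. The monocyte marker gene CD14 went from 25 to 10 and from 15 to 40 counts, a contrast of 2.72.

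EEF1E1-BLOC1S5, GTF2H2C and TVP23C-CDRT4 share most of their sequence with other genes, and BLOC1S5 overlaps the first of them, which raises the question of whether very large differences come from reads split between such genes. Between both 20% O2 libraries, where oxygen did not differ, 12 genes with at least 5 CPM had a log2 difference of 3 or more in size, and 7 of them (58.3%, exact 95% interval 27.7% to 84.8%) had a joined name or at least 50% of their sampled words in another gene, against 2.7% of the 10518 genes with at least 5 CPM in these libraries and a measured value. The interval treats these genes as independent. GTF2H2 and GTF2H2C, both among the 7, are copies that can trade the same reads, so the interval may be too narrow. Summed over copies, SMN1 and SMN2 differed by −0.10 between those libraries. The EEF1E1 and BLOC1S5 rows together differed by −0.13 after 1 day and −0.48 after 10 days at 1% O2. The GTF2H2, GTF2H2B and GTF2H2C rows together still differed in opposite directions, by 0.20 and −1.10, so a trade among these copies does not account for all of that difference. A trade of reads between copies is therefore a candidate explanation for some of these extremes. The other 5 of the 12, C3, PI3, SLPI, CSGALNACT1 and H3F3A, did not reach that limit of sharing. H3F3A had counts in 1 of the 5 libraries only, so its own value is uncertain. No biological explanation was tested for the opposite directions.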

How the results depend on the processing

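Leaving out genes that share sequence was chosen after seeing the data; the other alternatives were planned. The labels give no replicate numbers that pair libraries; the day term of the oxygen test compares 1% with 20% O2 within each day. No library can be left out of a difference between a pair. Genes past the size rule numbered, for the acute, reoxygenated against 20% O2 and day 10 against day 1 comparisons, 839, 1166 and 1057 without a filter (main 412, 671 and 609), 131, 229 and 234 with the filter of 5 CPM, 100, 219 and 213 with a prior count of 10, and 93, 188 and 210 with the authors' normalized values; the acute count was 651 with a prior count of 0.5 and 246 when the interval had to exclude 0. With the filter of 5 CPM the chronic count was 1987 (main 2993), chronic minus acute 1615 (2609) and reoxygenated against 1% O2 1468 (2337); fewer genes were then compared. The oxygen term called 130 genes, and 81 with DESeq2 size factors, 281 without a filter, 0 without the day term (462 at an unadjusted p under 0.05), 61 with all 5 libraries, 49 with DESeq2, 224 with limma-voom and from 0 to 4225 with 1 library left out, without the day term; the cause was not tested. All 130 were among the calls of limma-voom and of the unfiltered fit. In each fit with 1 library left out, the spread came only from the pair left at the same oxygen level, which differed in day. Retention of higher and lower genes (main 15.6% and 3.8%) was 9.3% and 1.8% with the filter of 5 CPM, 40.1% and 16.2% with a limit of log2 0.5, and 13.9% and 10.3% for genes chosen on the acute difference; it was 23.1% for higher genes against 20% O2 at day 1 and 2.0% for lower genes without those that share sequence. Of 684 list medians 675 stayed on the same side of their random range, 5 moved inside it and 4 outside. Of 1341 log2 differences of named genes 1307 stayed within their counting interval, 34 moved and none reversed. Of 94 oxygen-term values of named genes, 57 kept their call and 37 lost it. The acute and chronic correlation stayed within a factor of 1.5 in all 3 alternatives. The lowest depth, 7719797 in the reoxygenated library, limits genes under about 1 CPM.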

Other observations

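Genes in these first paragraphs were chosen after their values were seen, and so were the tests of the interferon pattern against the 20% O2 library of day 1 and against time in culture. Between day 1 and day 10 at 20% O2, the 4 genes named next were far apart, without a fixed list or test behind them: the complement gene C3 went from 183 to 2928 counts (log2 3.75), the protease inhibitor genes SLPI from 6 to 136 (3.87) and PI3 from 1 to 79 (4.52, interval 3.54 to 11.39), and S100P from 9 to 65 (2.38). In the reoxygenated library these had 3337, 92, 16 and 21 counts. PLCB4 (−2.15), KRTAP2-3 (−2.39) and ADGRF1 (−1.92) were lower at day 10.

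Of the 2011 genes higher after 10 days at 1% O2, 172 (8.6%) remained past the size rule in reoxygenated cells against both 20% O2 libraries, and of the 982 lower genes 15 (1.5%). Those with at least 5 CPM and no shared sequence numbered 65 and 1. The genes were selected with the 20% O2 library of day 10, and no simulated value for full return is given for these counts. CYP1A1 and CYP1B1, textbook targets of the aryl hydrocarbon receptor, were both among the retained higher genes. CYP1A1 had 104, 1033 and 260 counts at 20% O2, at 1% O2 and after reoxygenation, and CYP1B1 519, 1255 and 1654, not scaled to library depth. No fixed list was built for this receptor, and its activity was not tested. PDK4, NFATC4, DHRS3, CEMIP and COL4A5 were further members, with reoxygenated log2 differences of 1.85, 1.68, 1.62, 1.65 and 1.64, and the lower gene was ESM1 at −1.03.

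More genes were higher than lower after 10 days at 1% O2. Genomic DNA or other background reads would raise silent genes as well, but the summed olfactory receptor CPM was 0.58 times that at 20% O2 (interval 0.33 to 0.97), whereas other genes under a mean of 1 CPM stood at 2.12 times. Counting noise of low genes is argued against by the 66.4% higher among genes of at least 5 CPM, and the choice of scaling by 69.3%, the lower share with DESeq2 size factors or library totals. With the authors' normalized values, which also change how low counts are damped, the share was 60.9% (1380 of 2267). The share was 70.0% between both 20% O2 libraries too, so a share of this size was not particular to hypoxia. The counts differed, with 426 genes higher and 183 lower between those libraries. After 10 days at 1% O2, 2011 were higher and 982 lower. The cause was not tested further.

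Interferon-stimulated genes were higher in the reoxygenated library. A low level in the 20% O2 day 10 library is argued against by the median of 0.68 against the day 1 library. With the filter of 5 CPM the median was 0.51, above its random range. Genes could pass that filter through the reoxygenated library itself, the shallowest. The filter therefore cannot decide whether low counts in that library contributed. Time in culture cannot be told apart from reoxygenation: the list differed by a median of 0.01 between day 10 and day 1 at 20% O2, but no library had the full time at 20% O2. A response to the return of oxygen, to time or to this 1 culture may each underlie it.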
